A study of Mus musculus with 8 samples.

How the data were processed

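RNA sequencing was done on colon tissue of mice with colitis from dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium. The 8 libraries fall into 2 groups. The DSS group holds 4 libraries, and the DSS + GAA group holds 4 libraries from mice that also received ganoderic acid A (GAA), a triterpenoid of the fungus Ganoderma, at 20 mg/kg. Both groups carry the replicate numbers 1, 2, 4 and 5. The titles, the protocol and the design text give 20 mg/kg for the whole GAA group, while the treatment labels of its 4 libraries read 20, 21, 22 and 23 mg/kg, so the 4 were kept as 1 group. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase I, messenger RNA was taken with oligo(dT) beads, and libraries were sequenced in paired ends on an MGI-T7 instrument. The labels do not say whether the protocol kept strand, so reads of overlapping genes on opposite strands cannot be told apart.

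The authors deposited 1 table of 18262 genes with a TPM value per library. The TPM values of every library add up to the same total. TPM divides reads by transcript length and then by the library's total, so it keeps no record of sequencing depth, and the depth of each library is unknown. No interval or detection floor that needs counts could be given. The authors' deposited table also holds a log2 fold change, a p-value and a false discovery rate per gene for DSS + GAA over DSS. Over the 10458 genes above 5 TPM in both groups, the deposited log2 fold change differed from the log2 ratio of the mean TPM values by at most 0.00025. The deposited false discovery rate was the Benjamini-Hochberg adjustment of the deposited p-value over all 18262 rows. The test behind the deposited p-values is not given in the sources used here. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, Bowtie2, featureCounts, Subread, edgeR, SAMtools and GATK, and the genome build was mm10; the notes give no versions and no roles. Of the listed genes, 18121 matched a protein-coding gene in GENCODE vM21, and 77 had no match. Coordinates are those of that annotation, on GRCm38 (mm10).

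Genes with a TPM of at least 1 in at least 4 of the 8 libraries were tested, which kept 14217 genes and left out 4045. TPM values were put on the log2(TPM + 1) scale and compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with group as the sole term, a variance trend and robust empirical Bayes. Fold changes are on that scale, which understates the change of genes with low values. P-values are two-sided and adjusted by Benjamini-Hochberg over all tested genes, and an adjusted p under 0.05 counts as passing. Errors of TPM values are SD over 4 libraries, and errors of log2 fold changes are standard errors from the fit. Single genes named in the series title, and the IL-17 targets, were also compared with a two-sided exact permutation test over the 70 assignments of the 8 libraries, whose smallest p is 0.0286. The labels do not state that each library is a separate animal, so the p-values measure the spread between these samples.

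Before the data were examined, 44 gene lists were fixed: IL-17 and other inflammatory genes, immune, epithelial, stromal and neural cell types, tissues that could be carried along, and metabolic and stress genes. The 43 lists with at least 5 tested genes (sex-linked genes left out) were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, and fry, were alternatives. A further 2 lists, posterior Hox genes and ileal enterocyte genes, were added after the main result was seen and before their own values were. The genes named in the text follow a rule fixed before the data were examined. They are the 12 largest rises and 12 largest falls among genes with a symbol that passed, had a mean TPM of at least 2 and had fully separated groups. To these were added 7 genes of the series title's subject, and from each described list the 4 members with the smallest p and the commonest marker. Some genes that the rule takes are not reported here. A gene named outside the rule is marked as chosen after its values were seen.

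Alternatives were other pseudocounts, filters, scalings between libraries, empirical Bayes settings, array quality weights, a replicate block, removal of mitochondrial and haemoglobin genes, and leaving out each library. Median centring, and removal of each library's trend with transcript length and GC content (available for 14173 of the tested genes), were chosen after seeing the data. Count tests were not run, since the table holds no counts. On data simulated for this comparison over 14217 genes, the test recovered 50 of 100 genes changed by 1 on the log2 scale and 90 of 100 changed by 2, and it called 7 unchanged genes. The simulated noise was independent between genes, few genes were changed, none of them near the floor, and no scaling shift between libraries was set. The real data differ in these points, so the simulated rates may not carry over to them.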

Results

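Gene expression was measured by RNA sequencing in colon tissue of mice with DSS colitis, in 4 libraries of the DSS group and 4 libraries of mice that also received GAA at 20 mg/kg. The series asks, by its title, whether GAA eases colitis by lowering IL-17 signalling through the nuclear receptor RORA. Tissue of mice without colitis was not analysed here, so the comparison shows how the 2 colitis groups differ and gives no healthy level. Values are TPM as deposited, and sequencing depth is unknown. The first principal component of the log2 values held 64.0% of the variance and set the DSS libraries (-57.9 to -30.0) apart from the DSS + GAA libraries (5.28 to 61.9). The second held 19.1%, with DSS + GAA replicate 1 at its low end (-52.6). Across genes, which are not independent replicates, Pearson's r was 0.966 to 0.986 between DSS libraries, 0.923 to 0.989 between DSS + GAA libraries and 0.896 to 0.962 between the groups.

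Of the listed genes, 18 of 21 neutrophil and 13 of 18 inflammatory cytokine genes were lower in DSS + GAA colon, and 7 of 10 MHC class II and 14 of 21 T and NK cell genes were higher. The set tests of these 4 lists passed at the preset correlation and not with an estimated correlation (adjusted p = 0.447 for each). Of 14217 tested genes, 4006 were lower and 847 were higher in DSS + GAA (limma, adjusted p under 0.05), and 1402 of the lower and 284 of the higher genes changed by at least 1 on the log2 scale. On TPM as deposited, the groups were fully separated for 4678 genes, 32.9% of those tested. For 1 gene without a group difference, chance gives separation in 2.86% of cases. The share cannot be weighed against that value, since genes vary together and the trimmed mean scaling factors also separated the groups. These factors were 1.01 to 1.18 in the DSS and 0.868 to 0.967 in the DSS + GAA libraries. The median log2 fold change of all tested genes was -0.25, and the balance of the calls followed the scaling between libraries. Lower genes made up 82.5% of the calls on TPM as deposited, 50.5% after trimmed mean scaling (1709 higher, 1742 lower), 48.8% after quantile normalization (1677 higher, 1601 lower) and 37.7% after median centring (2165 higher, 1308 lower). No gene called on the deposited scale was called in the opposite direction under any of these 3 scalings. Leaving out DSS replicate 1 left 361 higher and 1676 lower genes. Higher genes also numbered 529 without DSS replicate 2, 545 without DSS + GAA replicate 4 and 1277 without DSS + GAA replicate 1. Lower genes numbered 2669 without DSS replicate 4, and 417 higher and 2430 lower genes were left without DSS + GAA replicate 2. The authors' deposited table calls 1883 genes higher and 2964 lower at a false discovery rate under 0.05. Of these, 1493 higher and 1906 lower genes passed the filter and were tested here. Among the tested ones, 794 of the higher and 1817 of the lower genes were also called here, and 0 were called in opposite directions.

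**Figure D1:**
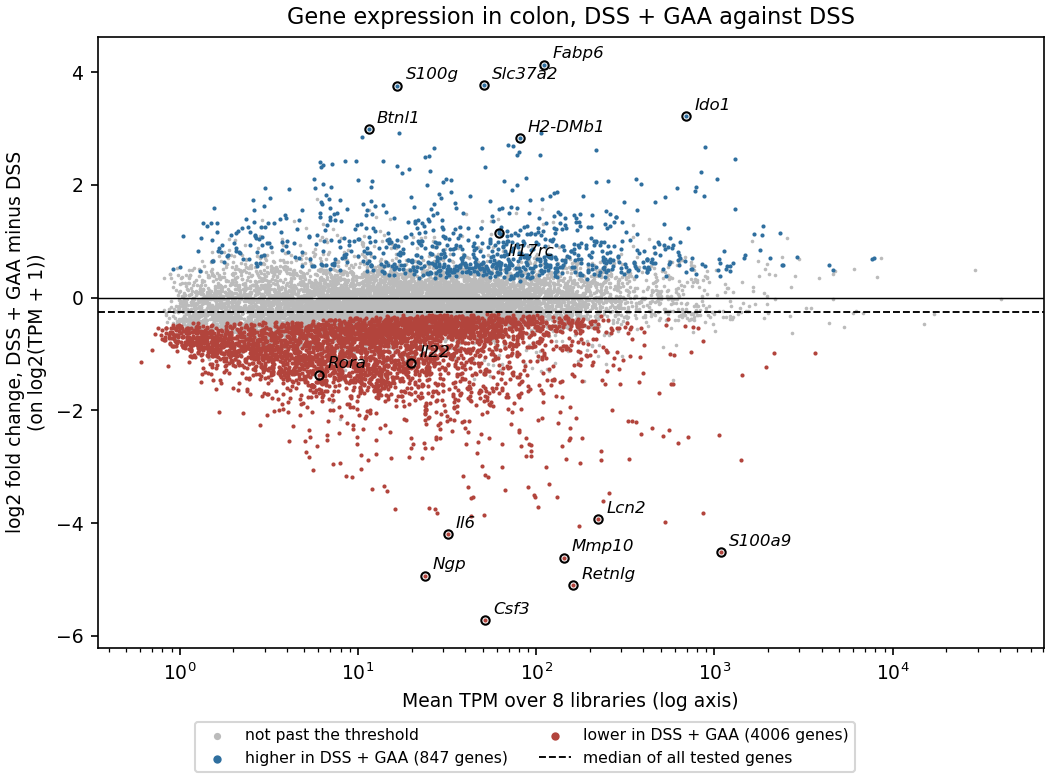
Each point is 1 of 14217 genes, with its mean TPM over 8 libraries on a log axis and its log2 fold change, DSS + GAA minus DSS, on the log2(TPM + 1) scale; blue and red points passed the test and the dashed line marks the median of all genes at -0.25. Csf3, Retnlg and Ngp lie lowest (-5.71, -5.10 and -4.93) and Fabp6 highest (4.13).

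Rora, the receptor of the series title, fell from 9.01 ± 2.06 TPM in DSS to 3.07 ± 1.72 TPM in DSS + GAA (SD, n = 4 per group; chromosome 9, 68653786 to 69388246, plus strand). Its log2 fold change was -1.37 ± 0.29 (limma adjusted p = 0.0101), and all 4 DSS libraries lay above the 4 DSS + GAA libraries. Among the cytokines, Il17a fell from 1.92 ± 1.01 to 0.39 ± 0.27 TPM, with 1 DSS + GAA library listed at 0 (log2 fold change -1.03 ± 0.26, limma adjusted p = 0.0163). The size of this fold change depended on the pseudocount, at -2.24 with a pseudocount of 0.1 and -0.351 with one of 5. Il22, which acts on epithelium, fell from 27.3 ± 4.11 to 12.4 ± 5.06 TPM (-1.16 ± 0.29, limma adjusted p = 0.0173). The receptor subunit gene Il17rc rose from 38.5 ± 7.27 to 85.5 ± 7.83 TPM (1.14 ± 0.14, limma adjusted p = 0.00460). Il17f (-0.22 ± 0.25, limma adjusted p = 0.503) and Il17ra (-0.21 ± 0.17, limma adjusted p = 0.358) did not pass, and the sign of both turned under quantile normalization and median centring, and that of Il17ra under trimmed mean scaling. The two-sided exact permutation p was 0.0286, the smallest possible, for Rora, Il17a, Il22 and Il17rc, and 0.457 for Il17f and 0.257 for Il17ra. Il17a missed the threshold under quantile normalization (limma adjusted p = 0.0739) and median centring (0.0701), and the filter left it untested without any DSS library or at a TPM of at least 5. Il22 missed it under trimmed mean scaling (0.0667), quantile normalization (0.0636), median centring (0.0729) and without DSS replicate 1 (0.0521).

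**Figure D2:**
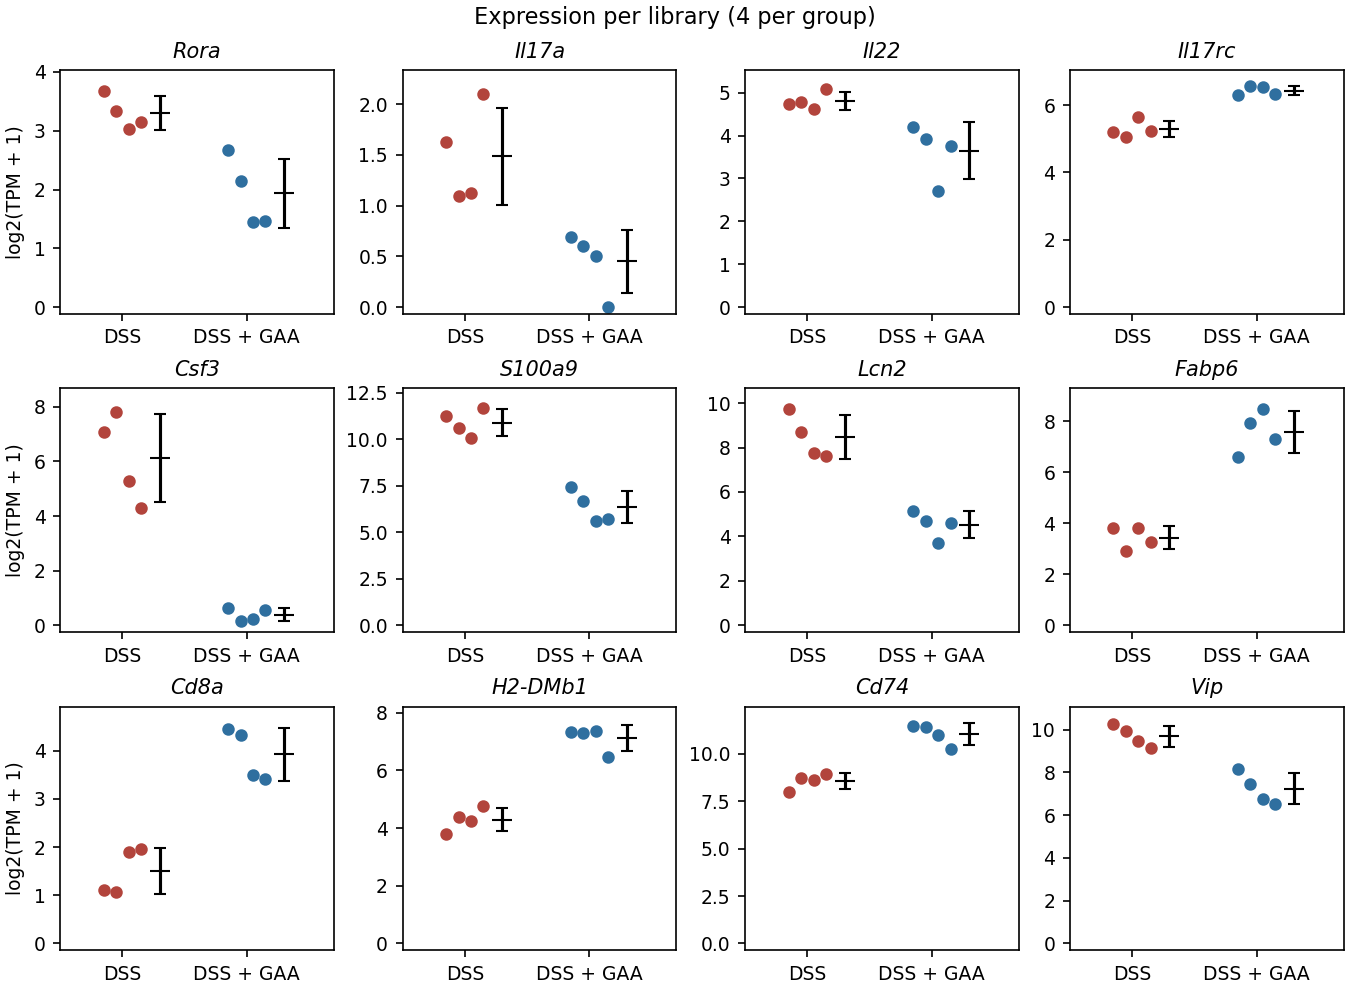
Points are log2(TPM + 1) of single libraries (4 per group) for 12 genes, and black bars are group means with SD. Rora, Il17a, Il22, Csf3, S100a9, Lcn2 and Vip lie lower, and Il17rc, Fabp6, Cd8a, H2-DMb1 and Cd74 higher, in each DSS + GAA library than in any DSS library.

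Most listed genes that IL-17 induces fell. Of 27 tested IL-17 targets, 19 fell, 0 rose and 8 did not pass (19 fell adjusted over the list alone). The 8 were Ccl7 (log2 fold change -1.12), Cxcl10 (-0.34), Tnfaip3 (-0.34), Ccl20 (-0.13), Reg3b (0.01), Zc3h12a (0.13), Nos2 (0.31) and Reg3g (0.78). They are named after their values were seen. S100a9 and S100a8, the subunits of calprotectin, fell from 2074 ± 992 to 93.8 ± 58.4 TPM and from 1616 ± 964 to 104 ± 41.2 TPM. Csf3, the granulocyte growth factor gene, fell from 103 ± 93.4 to 0.33 ± 0.22 TPM, and the neutrophil chemokine gene Cxcl5 from 545 ± 169 to 113 ± 4.92 TPM. The list's median lay 1.67 below that of all genes, written as -1.67 on the log2 scale (camera adjusted p = 4.69e-05 and adjusted p = 0.447 with an estimated correlation). The wider IL-17 signalling list, which shares 20 tested genes with the targets, had 36 of 72 members fall and 5 rise (39 and 5 adjusted over the list alone). Its risers included Il17rc and Ifng; its median lay at -0.22 relative to all genes (camera adjusted p = 0.0165 and adjusted p = 0.640 with an estimated correlation). Its set test gave 0.0589 without DSS replicate 2 and 0.0851 without DSS + GAA replicate 5. In this list, 24 genes fell under trimmed mean scaling and quantile normalization, 22 under median centring and 23 without DSS replicate 1.

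Neutrophil genes showed the lowest median of the 43 tested lists. Of 21 tested, 18 fell and 0 rose, and the median lay at -2.51 relative to all genes (camera adjusted p = 5.32e-07 and adjusted p = 0.447 with an estimated correlation; 18 fell and 1 rose adjusted over the list alone). Retnlg fell from 314 ± 211 to 8.16 ± 6.20 TPM and the granule protein gene Ngp from 47.2 ± 43.8 to 0.13 ± 0.10 TPM. The commonest neutrophil marker, Ly6g, did not pass (3225 ± 909 and 2238 ± 1102 TPM, log2 fold change -0.62, limma adjusted p = 0.195). Its TPM lay above that of S100a9 in both groups (S100a9 at 2074 in DSS and 93.8 in DSS + GAA). Whether neutrophils alone gave the Ly6g signal in this tissue was not tested. Of 18 inflammatory cytokine genes, 13 fell and 1 rose (the same counts adjusted over the list alone; median -1.68 relative to all genes; camera adjusted p = 0.0104 and adjusted p = 0.447 with an estimated correlation). Il6 fell from 61.7 ± 44.1 to 1.91 ± 1.48 TPM and Il1a from 34.5 ± 15.6 to 5.07 ± 1.99 TPM, while Ifng, the type II interferon gene, rose from 1.21 ± 0.31 to 11.5 ± 6.20 TPM. In the cytokine list 8 genes fell without DSS replicate 1, and its set test gave 0.135 without DSS replicate 2 and 0.0848 without DSS replicate 4.

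The largest falls included Csf3, Retnlg, Ngp, Mmp10, S100a9, Il6, Mmp13, Saa3, Lcn2, Chil1 and Mmp8, with log2 fold changes from -5.71 to -3.83. They include the matrix metalloproteinases Mmp10 (278 ± 247 to 7.55 ± 3.65 TPM) and Mmp13 (333 ± 287 to 14.7 ± 6.94 TPM), and Lcn2, the siderophore-binding lipocalin (422 ± 310 to 23.6 ± 9.33 TPM). The 12 largest rises were Fabp6, Slc37a2, S100g, Ido1, Btnl1, Tgtp1, Trpv6, H2-DMb1, Tnfsf10, Ubd, Cyp4f14 and Apol10a, with log2 fold changes from 2.62 to 4.13. Fabp6, an intestinal bile acid-binding protein (chromosome 11, 43596049 to 43601540, minus strand), rose from 10.2 ± 3.26 to 212 ± 113 TPM. The tryptophan-degrading enzyme gene Ido1 rose from 117 ± 62.7 to 1268 ± 810 TPM. Epithelial calcium handling genes S100g and Trpv6 rose from 0.53 ± 0.19 to 32.8 ± 27.3 TPM and from 1.52 ± 1.42 to 19.5 ± 13.1 TPM. Limma adjusted p-values of the 24 largest rises and falls lay between 0.00305 and 0.0117, and 0 of the 24 lost their call under an alternative in which they were tested. The filter left Csf3 and Ngp untested without any DSS library, S100g untested without any DSS + GAA library, and S100g and Trpv6 untested at a TPM of at least 5.

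Most listed MHC class II and T and NK cell genes rose. Of 10 MHC class II genes, 7 rose and 0 fell (the same counts adjusted over the list alone; median 2.04 relative to all genes; camera adjusted p = 2.16e-10 and adjusted p = 0.447 with an estimated correlation). Cd74, the invariant chain, rose from 391 ± 101 to 2220 ± 760 TPM, and the peptide exchange factor genes H2-DMb1 and H2-DMa from 19.2 ± 5.55 to 142 ± 37.2 TPM and from 5.84 ± 1.89 to 32.7 ± 9.47 TPM. Of 21 T and NK cell genes, 14 rose and 0 fell (the same counts adjusted over the list alone; median 1.27 relative to all genes; camera adjusted p = 1.43e-11 and adjusted p = 0.447 with an estimated correlation). Cd8a rose from 1.96 ± 0.97 to 15.0 ± 5.84 TPM, Cd8b1 from 1.29 ± 0.41 to 11.1 ± 5.02 TPM and Nkg7 from 3.76 ± 0.66 to 20.1 ± 8.42 TPM, while Cd4, named after its value was seen, did not pass (log2 fold change -0.23). T and NK cell genes that rose numbered 9 without DSS replicate 1 and 8 without DSS + GAA replicate 2.

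Of 35 interferon response genes, 10 rose, 1 fell and 24 did not pass (the same counts adjusted over the list alone; median 0.84 relative to all genes; camera adjusted p = 6.50e-09 and adjusted p = 0.524 with an estimated correlation). Cxcl9 rose from 21.7 ± 11.7 to 139 ± 62.1 TPM and Igtp from 125 ± 39.8 to 603 ± 297 TPM. The number of risers was 2 without DSS replicate 1, 4 without DSS replicate 2 or DSS + GAA replicate 2, 6 without DSS + GAA replicate 4 and 19 without DSS + GAA replicate 5. In this list 0 genes fell under each of the 3 other scalings and without DSS replicate 1, 4 or 5 or DSS + GAA replicate 2 or 5, and 2 without DSS + GAA replicate 1.

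Some epithelial and respiratory chain genes rose. Of 32 colonocyte genes, 7 rose and 3 fell (6 and 3 adjusted over the list alone; median 0.70 relative to all genes; camera adjusted p = 1.99e-06 and adjusted p = 0.447 with an estimated correlation). The sodium channel gene Scnn1a rose from 36.6 ± 6.68 to 104 ± 4.38 TPM and the proton pump gene Atp12a from 259 ± 79.8 to 978 ± 152 TPM, while the carbonic anhydrase gene Car1 fell from 2704 ± 412 to 1200 ± 490 TPM. Of 19 goblet cell genes, 6 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.71 relative to all genes; camera adjusted p = 1.34e-06 and adjusted p = 0.447 with an estimated correlation). Agr2 rose from 1464 ± 406 to 3173 ± 435 TPM and Fcgbp, a mucus protein gene, from 316 ± 147 to 730 ± 151 TPM. The mucin gene Muc2 did not pass (log2 fold change 0.62). Of 44 nuclear respiratory chain genes, 19 rose and 0 fell (23 and 0 adjusted over the list alone; median 0.71 relative to all genes; camera adjusted p = 3.51e-18 and adjusted p = 0.447 with an estimated correlation), among them Cox7b (364 ± 22.1 to 620.5 ± 115 TPM). The 13 mitochondrially encoded genes gave 0 calls in either direction in limma. Among them mt-Nd6 had the smallest p (log2 fold change -0.52, limma adjusted p = 0.0526). It passed under quantile normalization (0.0377), with no variance trend and no robust fit (0.0440), with the length and GC trends removed (0.0289) and without DSS replicate 4 (0.0428) or DSS + GAA replicate 5 (0.0462). Others passed too, mt-Nd5 under quantile normalization (0.0303), and mt-Nd1 (0.0387) and mt-Nd3 (0.0496) with the length and GC trends removed.

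These counts leaned on scaling and on single libraries. Colonocyte falls numbered 1 under trimmed mean scaling or median centring and without DSS replicate 1, 4 or 5 or DSS + GAA replicate 2 or 4. Under median centring 15 colonocyte and 37 respiratory chain genes rose, and under trimmed mean scaling 34 respiratory chain genes. Without DSS replicate 1, 4 colonocyte, 3 goblet cell and 5 respiratory chain genes rose. Colonocyte risers numbered 13 without DSS replicate 5, and goblet cell risers 3 without DSS + GAA replicate 2. Respiratory chain risers numbered 12 without DSS replicate 2 or 5, 7, 9 and 10 without DSS + GAA replicate 2, 4 and 5, and 37 without DSS + GAA replicate 1.

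Most listed genes of enteric neurons and glia, matrix and fibroblasts, endothelium and red blood cells fell. Of 23 genes of enteric neurons and glia, 21 fell and 0 rose (22 and 0 adjusted over the list alone; median -1.31 relative to all genes; camera adjusted p = 1.38e-07 and adjusted p = 0.447 with an estimated correlation). The neuropeptide gene Vip fell from 866 ± 298 to 165 ± 87.7 TPM. Of 30 matrix and fibroblast genes, 18 fell and 0 rose (22 and 0 adjusted over the list alone; median -1.27 relative to all genes; camera adjusted p = 0.000116 and adjusted p = 0.652 with an estimated correlation), among them Lox (80.4 ± 67.5 to 5.44 ± 4.03 TPM); 10 fell without DSS replicate 1. Of 19 endothelial genes, 15 fell (17 adjusted over the list alone; median -0.93 relative to all genes; camera adjusted p = 0.00128 and adjusted p = 0.652 with an estimated correlation), and 6 fell under trimmed mean scaling, quantile normalization or median centring. Endothelial falls numbered 4 without DSS replicate 1, 7 without DSS replicate 4 or DSS + GAA replicate 4 or 5, and 9 without DSS + GAA replicate 2. Of 6 erythroid genes, 5 fell (5 adjusted over the list alone; camera adjusted p = 0.0101 and adjusted p = 0.447 with an estimated correlation), and haemoglobin transcripts, whose near-identical copies share reads, summed to 189 to 382 TPM in DSS and 9.36 to 62.2 TPM in DSS + GAA. Of 19 immediate early and heat shock genes, 12 fell (12 adjusted over the list alone; median -0.64 relative to all genes; camera adjusted p = 0.0107 and adjusted p = 0.447 with an estimated correlation), and 7 without DSS replicate 1 or under trimmed mean scaling or median centring. Dusp1 fell from 260 ± 129 to 34.1 ± 14.5 TPM and Fos from 248 ± 65.0 to 104 ± 13.4 TPM.

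**Figure D3:**
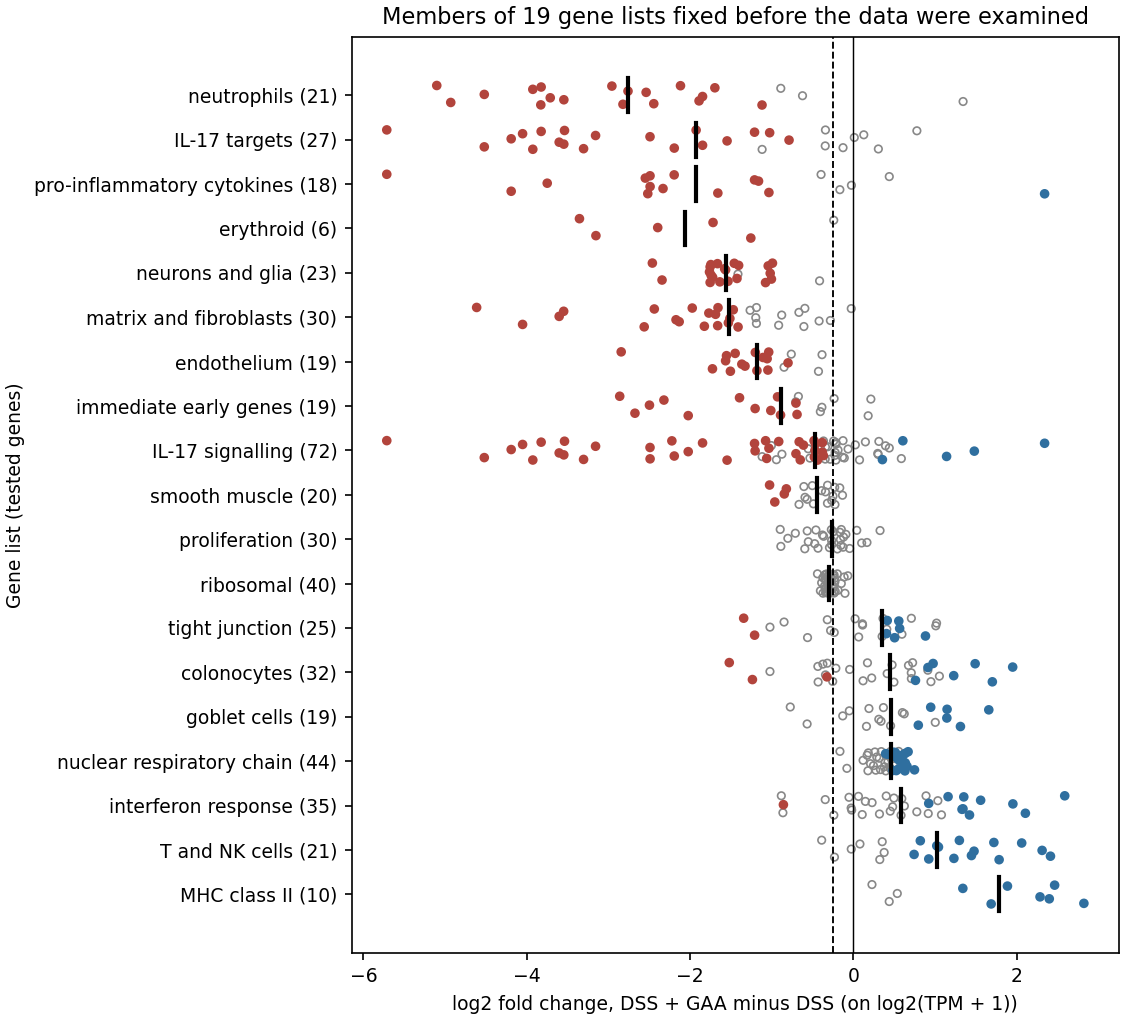
Each point is the log2 fold change of 1 gene, DSS + GAA minus DSS on the log2(TPM + 1) scale, in 19 lists with their number of tested genes; filled points passed the test, black bars are list medians and the dashed line is the median of all genes at -0.25. Neutrophil genes have a median of -2.76 and MHC class II genes one of 1.79; the ribosomal median (-0.30) turns positive under median centring, and the proliferation median (-0.27) under quantile normalization and median centring.

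Cell cycle and ribosomal genes gave no call. Of 30 proliferation genes and 40 ribosomal protein genes, 0 passed in limma, with medians -0.02 and -0.05 relative to all genes, and the smallest limma adjusted p-values belonged to Rrm2 (0.0740) and Rpl27 (0.0871). Rrm2 passed with array quality weights (0.0376) and without DSS replicate 5 (0.0253), and Rpl27 with the length and GC trends removed (0.0352). The set test of the proliferation list pointed up (camera adjusted p = 0.474) while its median and mean were negative, and 1 of its genes rose under each of the 3 other scalings and without DSS + GAA replicate 1, and 1 fell without DSS replicate 5 or DSS + GAA replicate 4. Of 20 smooth muscle genes, 4 fell, and 2 under quantile normalization and 0 under trimmed mean scaling or median centring. With 1 library left out, 0 fell without DSS replicate 1 or 4 or DSS + GAA replicate 4 or 5, 1 without DSS replicate 5, 2 without DSS + GAA replicate 2 and 7 without DSS + GAA replicate 1. Of 15 B and plasma cell genes, 1 fell (Sdc1, 148 ± 23.3 to 74.2 ± 10.4 TPM) and 0 rose, with 3 falling without DSS + GAA replicate 1 and 1 rising under quantile normalization or median centring. With an estimated correlation 0 of the 20 lists called by camera at the preset correlation passed. Fry called 18 lists, but not all of them were among those 20. Fry tests a list against no change, while camera compares it with the other genes, so their calls are not interchangeable. The median log2 fold change of all tested genes was -0.25. Fry did not call the interferon response (fry adjusted p = 0.297), goblet cell (0.0871), colonocyte (0.0730), respiratory chain (0.0641) and tight junction (0.0743) lists. Nor did fry call the xenobiotic (0.0633), sterol (0.206), fatty acid (0.639) and pancreas (0.0727) lists. Lists that fry called and camera did not included crypt stem cell genes (fry adjusted p = 0.00140). Other groupings of the 8 libraries called up to 26 lists, so the set tests do not by themselves tie a list to the treatment.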

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

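The tests on genes outside the neutrophil list and on the muscle wall, and the median centring and length and GC alternatives, were chosen only after the result was seen, as was the reading of the length, GC and Hox tests of the first and last pattern as open. Of 442 groups of 4 samples tested for 1 sample far from the others (Dixon's ratio above 0.829), 22 passed, and chance passes about 1 in 20. Among immune and muscle genes, in TPM, H2-DMb1 was 86.5 in DSS + GAA replicate 5 (others 158 to 164), Cxcl9 was 48.8 there (150 to 184) and Mb was 2.92 there (12.6 to 15.4), and Mcpt1 was 8.95 in DSS replicate 1 (3.77 to 4.15). Among epithelial genes, Agr2 was 2520 in DSS + GAA replicate 1 (3320 to 3440) and Marveld3 was 51.7 there (61.0 to 62.7). Bcas1 was 98.2 in DSS + GAA replicate 4 (144 to 150), Scnn1a was 97.1 there (105 to 107), and Cldn3 was 167 in DSS replicate 1 (233 to 244). Mcm7 was 18.7 TPM in DSS + GAA replicate 4 (11.3 to 11.8). In DSS replicate 2, Cela2a was 3.34 TPM (4.10 to 4.16) and Rpl37 was 507 TPM (431 to 441). Fosb was 14.8 TPM in DSS replicate 5 (4.20 to 5.08) and Fos was 152 TPM in DSS replicate 4 (272 to 294). In DSS + GAA replicate 5, Gpx4 was 117 TPM (101 to 103), Cyp3a13 was 174 TPM (143 to 144) and Cpt2 was 95.5 TPM (76.9 to 78.7). Among summed lists, dendritic cell genes were 117 TPM (90.8 to 92.6) and adipose genes 482 TPM (666 to 707) in DSS replicate 5. Immediate early genes summed to 1210 TPM in DSS + GAA replicate 4 (1270 to 1280). In DSS replicate 2, oxidative stress genes summed to 7170 TPM (6790 to 6810) and NF-kB genes to 3390 TPM (2980 to 3040).

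More genes were lower than higher in DSS + GAA, 82.5% of the calls on TPM as deposited. Removing each library's trend with transcript length left 82.1% (76.7 to 86.4 with 1 library left out), and removing the trend with GC content left 82.8% (77.6 to 86.9), but these corrections keep each library's median, which the share follows, so both biases stay open. After median centring the share was 37.7% (23.3 to 44.8), so the scaling of TPM may account for the imbalance. A real drop in many transcripts would be hidden by centring too, and without counts or an added standard it stays open.

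IL-17 target genes were lower in DSS + GAA. The 23 targets outside the neutrophil list (15 fell, 0 rose) had a median of -1.30 relative to all genes (-1.55 to -0.979 with 1 library left out). The fall was thus not confined to the 4 targets shared with that list. The test was chosen after large falls among the 23 were seen, and whether neutrophils express them too was not tested. It therefore cannot decide whether fewer neutrophils alone were the cause. With the trends in length and GC content removed, the median of all 27 targets was -1.69 (-1.88 to -1.43), against -1.67 before, which argues against those biases. As a hypothesis, lower inflammatory signalling in the tissue may contribute, yet less inflamed tissue at the start and other changes in cell make-up were not tested.

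Neural and matrix genes were lower in DSS + GAA. The smooth muscle median lay 1.13 above the neural median (0.885 to 1.39 with 1 library left out). Smooth muscle genes thus fell less than neural genes. This comparison was chosen after the list values were seen and left out the matrix genes. It therefore cannot decide whether a smaller share of muscle wall in the pieces was the source. Of 5 genes of interstitial cells of Cajal, which also belong to the muscle wall, 4 fell (median -0.64 relative to all genes). Under each of the 3 other scalings 2 of these fell and 1 rose, so a smaller share of muscle wall is not excluded as a source. Posterior Hox genes (11 tested, 1 rose, 4 fell) had a median of 0.0927 relative to all genes (0.0335 to 0.0994), where tissue from nearer the ileum predicts a low value, but the members went both ways and 1 to 2 fell under the 3 other scalings, so this stays open. After removal of the length and GC trends the neural median relative to all genes was -1.27 (-1.68 to -1.11), against -1.31 before. A different mix of tissue layers other than muscle, or a response to GAA, may contribute and was not tested.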

How the results depend on the processing

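Median centring and removal of the length and GC trends were chosen only after the result was seen. The causes of the changes listed here were not tested, except that leaving out a library reduces the sample number. Genes higher and lower numbered 1709 and 1742 under trimmed mean scaling, 1677 and 1601 under quantile normalization, and 2165 and 1308 under median centring, against 847 and 4006 on TPM as deposited. With 1 library left out they ranged from 361 to 1277 and from 1676 to 4435. The adjusted p of the IL-17 signalling list, set test (0.0165), was 0.640 for camera with an estimated correlation. It was 0.00802 without DSS replicate 5 and 0.0851 without DSS_GAA replicate 5, the ends of its range with 1 library left out, and between 0.000288 (quantile normalization) and 0.0343 (array quality weights) under the other settings. The set test called 20 lists, 19 to 25 with 1 library left out and 0 with an estimated correlation. Of the 33 tested genes of the title's subject, 23 passed, and 20 to 24 with 1 library left out. The sign of Il17ra turned to 0.00408 under trimmed mean scaling, 0.179 under quantile normalization and 0.0887 under median centring, and that of Il17f to 0.203 and 0.0779 under the latter pair; neither gene passed the test. Over 175 named genes, 3244 of 3436 values kept direction and side of the threshold, 159 lost the call, 28 gained one and 5 changed sign. Over 19 lists, 373 of 377 did and 4 lost the call, all with camera at the preset correlation. This tally leaves out the estimated correlation, with which 0 lists passed, and fry, which did not call some of these lists. The array quality weights did not fully converge. TPM keeps no depth, so whether depth limits the genes with low values is unknown, and count tests were not run.

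With the replicate number as a replicate block, 679 genes were higher and 3340 lower. The deviations of same-numbered libraries from their group means correlated at 0.180, -0.109, 0.146 and -0.030, and 4 of 8 libraries correlated best with their own number, so the numbers were not read as pairs.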

Other observations

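The tests listed here were set before their own values were seen, but the ileal enterocyte list, and the reading of its test as open, were chosen only after the result was seen. Clock genes, some of which RORA regulates, fell in part: of 19 tested, 6 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.966 and adjusted p = 0.969 with an estimated correlation). Their median of -0.30 turned positive under median centring. Per1 fell from 36.3 ± 11.4 to 13.8 ± 0.95 TPM, Cry2 from 18.4 ± 6.34 to 6.24 ± 0.58 TPM and Nfil3 from 66.9 ± 33.0 to 12.4 ± 6.91 TPM (SD, n = 4 per group). Of 14 Th17 genes 9 fell and 1 rose (camera adjusted p = 0.119), and 5 fell under trimmed mean scaling, 3 under quantile normalization or median centring, 4 without DSS replicate 1 and 5 without DSS replicate 2. Of 9 IL-17 cytokine and receptor genes 3 fell and 1 rose (camera adjusted p = 0.708), with the test pointing up while the median was -0.21, a sign that turned under each of the 3 other scalings. In this list 2 fell under trimmed mean scaling, 0 under quantile normalization, 1 under median centring and 1 without DSS replicate 1, 4 or 5, and 2 rose without DSS + GAA replicate 5. Of 31 chemokine genes 12 fell and 4 rose (camera adjusted p = 0.585), with Cxcl1 at 218 ± 137 and 19.3 ± 10.1 TPM, and 1 rose and 8 fell without DSS replicate 1. Of 24 macrophage genes 7 fell (camera adjusted p = 0.585), among them Arg1 (16.4 ± 12.5 to 0.66 ± 0.19 TPM), and 3 fell under each of the 3 other scalings. With 1 library left out, macrophage falls ranged from 2 (DSS replicate 1) to 13 (DSS + GAA replicate 1), with 3 without DSS replicate 2, 4 or 5 or DSS + GAA replicate 4 and 4 without DSS + GAA replicate 5. Of 29 NF-kB and inflammasome genes 6 fell and 2 rose (camera adjusted p = 0.438, pointing up while the median was -0.19, which turned positive under trimmed mean scaling and median centring), with Il1b lower (262 ± 102 to 46.3 ± 23.0 TPM) and Casp1 higher (230 ± 28.9 to 505 ± 86.7 TPM). The balance of this list turned to 4 rising and 3 falling under trimmed mean scaling and 4 and 2 under median centring, and its risers numbered 4 without DSS + GAA replicate 5 and 1 without DSS replicate 1 or DSS + GAA replicate 2 or 4.

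In epithelium, 7 of 16 crypt stem cell genes fell and 0 rose (camera adjusted p = 0.106), with Smoc2 falling from 29.7 ± 15.1 to 6.48 ± 0.98 TPM, and 3 fell under trimmed mean scaling or median centring, 4 under quantile normalization and 4 without DSS replicate 1. Of 18 fetal and regeneration genes 9 fell and 1 rose (camera adjusted p = 0.301), and Msln fell from 19.4 ± 9.54 to 1.30 ± 0.32 TPM. The riser of this list was lost under quantile normalization and without DSS replicate 1, 2 or 4 or DSS + GAA replicate 2, and 2 rose under median centring. Of 18 enteroendocrine and tuft cell genes 9 fell and 1 rose (camera adjusted p = 0.322), with somatostatin (Sst) at 84.9 ± 22.2 and 21.6 ± 11.8 TPM. In this list 4 fell under each of the 3 other scalings, 3 without DSS replicate 1, 4 without DSS replicate 2, 5 without any other library but DSS + GAA replicate 1 and 11 without that one, and 0 rose without DSS replicate 1 or 5 or DSS + GAA replicate 2 or 5. Of 25 tight junction genes 6 rose and 2 fell (camera adjusted p = 0.000166 and adjusted p = 0.447 with an estimated correlation), with 10 rising and 1 falling under trimmed mean scaling, 12 and 0 under median centring and 7 and 0 under quantile normalization. Tight junction risers numbered 1 without DSS replicate 1 or DSS + GAA replicate 2, 2 without DSS + GAA replicate 4, 3 without DSS replicate 2 and 9 without DSS + GAA replicate 1, where 5 fell. The set test of this list gave 0.0508 under quantile normalization, where that of the fatty acid list gave 0.157. Of 30 xenobiotic genes 10 rose and 3 fell (camera adjusted p = 1.82e-07 and adjusted p = 0.447 with an estimated correlation), among them Cyp3a13 (66.1 ± 8.32 to 151 ± 15.5 TPM); 6 rose without DSS replicate 1 and 18 without DSS + GAA replicate 1, and 1 fell without DSS replicate 1 and under each of the 3 other scalings. Of 24 sterol synthesis genes 4 rose (camera adjusted p = 7.52e-08 and adjusted p = 0.447 with an estimated correlation), and 9 under trimmed mean scaling or median centring. Sterol risers numbered 1 without DSS replicate 1, 2 without DSS replicate 2 or 5 or DSS + GAA replicate 2, 4 or 5, and 17 without DSS + GAA replicate 1. Of 23 fatty acid genes 5 rose and 6 fell, with a median of 0.24, a mean of -0.11 and a test pointing up (camera adjusted p = 0.00522 and adjusted p = 0.447 with an estimated correlation). The balance of this list turned to 10 rising and 3 falling under median centring, 9 and 4 under trimmed mean scaling and 6 and 4 under quantile normalization. Its risers numbered 2 without DSS replicate 1, 2 or 5 or DSS + GAA replicate 2 or 5, and 3 without DSS + GAA replicate 4, and 3 genes fell without DSS replicate 1. Of 22 antimicrobial genes 8 fell and 2 rose, with a negative median, turned positive under trimmed mean scaling, median centring and without DSS replicate 4 or 5, and a test pointing up (camera adjusted p = 0.842). Antimicrobial falls numbered 5 without DSS replicate 1, 2 or 5, and risers 4 without DSS replicate 5 or under median centring and 1 under quantile normalization or without DSS replicate 1 or 2 or DSS + GAA replicate 2 or 4. Of 11 adipose genes 4 fell and 0 rose (camera adjusted p = 0.539), among them Fabp4 (406 ± 104 to 57.5 ± 25.9 TPM), and the negative median of this list turned positive under quantile normalization.

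Of 6 pancreas genes 1 rose, Sycn (63.0 ± 25.5 to 134 ± 41.7 TPM), with a camera adjusted p of 0.00128 (adjusted p = 0.447 with an estimated correlation), and this list also holds the goblet cell gene Zg16. Pancreas risers numbered 0 without DSS replicate 1 or 2 or DSS + GAA replicate 2 or 5, 2 without DSS + GAA replicate 1 and 3 under quantile normalization or median centring. Of 10 dendritic cell genes 2 rose and 3 fell (camera adjusted p = 0.358), with 1 falling under each of the 3 other scalings and without DSS replicate 1 or DSS + GAA replicate 2, 4 or 5. Dendritic risers numbered 0 without DSS replicate 1 or 4 or DSS + GAA replicate 2, and 1 without DSS replicate 2 or DSS + GAA replicate 1, 4 or 5. Of 7 mast cell and eosinophil genes 1 rose and 1 fell (camera adjusted p = 0.106), with 0 falling under each of the 3 other scalings and without DSS replicate 1 or 4 or DSS + GAA replicate 2 or 4, and 2 rising under quantile normalization, median centring or without DSS replicate 1. Of 5 genes of interstitial cells of Cajal 4 fell and 0 rose (camera adjusted p = 0.358), while 2 fell and 1 rose under each of the 3 other scalings, 2 fell without DSS replicate 1 or 4 or DSS + GAA replicate 2 or 4, and 1 rose without DSS + GAA replicate 1. Of 9 skeletal muscle genes 3 rose and 3 fell (camera adjusted p = 0.242), and 4 rose and 0 fell under quantile normalization or median centring. Of 5 squamous epithelium genes 1 rose and 2 fell (camera adjusted p = 0.871), and the riser was lost under quantile normalization and without DSS replicate 1 or 2 or DSS + GAA replicate 2 or 4. Of 22 endoplasmic reticulum stress genes 3 rose and 2 fell (camera adjusted p = 0.106), with 1 rising without DSS replicate 1 or DSS + GAA replicate 2 and 1 falling under trimmed mean scaling or median centring. Of 24 oxidative stress genes 1 rose and 3 fell (camera adjusted p = 0.0572), with 4 rising under trimmed mean scaling or median centring, 2 under quantile normalization or without DSS + GAA replicate 4 and 5 without DSS + GAA replicate 1. In other lists, 1 gene more rose for clock genes and adipose genes without DSS replicate 5, for inflammatory cytokine and neutrophil genes without DSS + GAA replicate 5, for crypt stem cell genes without DSS + GAA replicate 1, for adipose genes under median centring, and for macrophage genes without DSS replicate 5 and under each of the 3 other scalings. Of the goblet cell genes 1 fell without DSS replicate 5, and of the immediate early genes 1 rose under trimmed mean scaling or median centring. Tight junction falls numbered 0 without DSS replicate 1 and 1 without DSS replicate 5 or DSS + GAA replicate 4.

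Other splits of the 8 libraries into 4 and 4 were counted for each result of the fit. Of 35 splits, 1, the real split, reached 847 higher genes, 1 reached 4006 lower genes and 1 reached 23 genes of the title's subject. Each other split gave 0. Those splits mix the 2 groups, so a group difference widens the spread within each side and lowers the calls. The counts of 0 are therefore no measure of chance, and 1 of 35 is the smallest share possible. For the IL-17 signalling list, 11 splits gave a set test p as small as 0.0165 (smallest other 2.88e-05), and 19 splits called at least 20 lists (highest other 26). The set tests with a preset correlation are therefore also passed by groupings that mix the treatments, and chance is not excluded for them.

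The rise of Fabp6, a gene most active in the ileum, raised the hypothesis that small intestine tissue was present in some pieces. Of 14 tested ileal genes other than Fabp6, 5 rose and 2 fell, with a median of 0.818 relative to all genes (0.674 to 0.993 with 1 library left out). The value set beforehand for such tissue was above 1, which the median did not reach with any library left out, though 0.993 lay close to it. The genes went both ways, so the hypothesis stays open. Without DSS replicate 1 or DSS + GAA replicate 2, 3 of these genes rose. Apob was 16.9 ± 7.64 and 86.1 ± 33.1 TPM, while the ileal bile acid transporter gene Slc10a2 was 135 ± 57.7 and 24.6 ± 10.5 TPM in DSS and DSS + GAA.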
